A study of Homo sapiens with 3 samples.

How the data were processed

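RNA was taken from 3 primary cultures of human epididymis epithelial cells, the cells that line the duct in which sperm mature. Per the labels' protocols the cultures were untreated, total RNA was extracted with Trizol and cleaned by filter centrifugation, and each culture was labelled with Cy3 and hybridised to its own 1-colour NimbleGen expression array of 60-base probes. The same cultures were used for mapping open chromatin, per the labels' protocols, and that part of the study is not used here. All 3 samples carry the same labels and form 1 group. The labels give no treatment, control or other contrast. They call the samples separate primary cultures but do not say whether these came from different donors, so no p-value extends beyond these 3 arrays to other donors.

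The authors deposited 1 table with 24000 rows, each a RefSeq transcript accession, and 1 column for each culture. The deposited values were taken as log2 intensities, because they lie between 3.10 and 15.86, the range of a 16-bit scanner on a log2 scale. The background correction, the normalization, the summary of probes into rows and the software are not given in the sources used here. The medians of the 3 columns were 9.61, 9.74 and 9.61, and their quartiles were similar but not identical. No scanner output was used, so neither spot quality nor a detection call per probe was at hand, and the number of arrays limits the precision. The columns were compared before averaging and no pair of arrays held the same values.

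Accessions were matched without version numbers to a table of human genes (assembly GRCh38.p14), used for names only. Of the 24000 rows, 19125 matched 1 gene symbol, none matched several and 4875 matched no symbol (2170 NM and 2705 XM accessions, the second kind being predicted transcripts). Rows of 1 gene were averaged on the log2 scale, which concerned 1464 genes, and 17217 genes entered the tests. No coordinates are given, because the arrays were designed on another genome build than the table's. Levels of genes on the Y chromosome and of XIST were left out of all gene tables.

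Because the design has no second group, the tests asked which genes gave signal above a background reference. The reference was, on each array, the 95th percentile of the 364 measured olfactory receptor genes, odorant receptors that were assumed to be silent in these cells. Each gene's log2 value minus its array's reference was fitted with an intercept in limma 3.58.1 (R 4.3.3) with eBayes, tested one-sided for a mean above 0 and adjusted by Benjamini-Hochberg over the 17217 genes at 0.05. The references differed by 1.51 between arrays, and this offset entered the residual of each gene. The fitted prior had infinite degrees of freedom, every gene had the same SE of 0.583, and a gene was called when its mean lay at least 1.14 above the mean reference of 8.76. The p-values therefore rank genes by their mean, take no account of a gene's own spread, and treat an offset shared by all genes as if it were known from many arrays. On simulated arrays with the real means and spreads of these 17217 genes, 1.00% of 200 genes placed at the mean reference were called. Of genes placed 1, 1.5 and 2 log2 units above it, 20.0%, 94.5% and 98.5% were called. Each gene was drawn singly and the references were held as observed, so silent probes that move with the reference were not covered. The 1.00% is therefore no error rate for silent genes. Of 90 bitter taste receptor and keratin-associated protein genes, also taken as silent, 10 were called on the real arrays.

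Probes differ in how well they hybridise, so a log2 value was used to place a gene above or below the reference and within the array's distribution, and not as transcript abundance. A gene that was not called can still be transcribed. In total 25 gene lists (cell types, transcription factors, transport, secretion, defence and housekeeping pathways) were fixed before the data were examined. So were the rule for named genes and the tests and alternatives, except those said below to be chosen after the values were seen. Called members of each list were counted, compared with the other genes by a two-sided Fisher's exact test, and adjusted over the 25 lists. A list's median percentile of signal was placed among 10000 random lists of the same size. Its median SD over the cultures was placed among 10000 lists matched on mean signal in 20 bins. Genes were named by rule: 29 key genes, the 3 called members of each list with the highest mean and the member with the lowest, the 10 genes with the highest mean other than ribosomal proteins, and the 10 called genes with the largest range between cultures. Some genes that meet the rule are left out of the text and figures, but all entered the tests and counts. Genes on the Y chromosome, XIST, HLA genes and genes of common deletion or splice variants were barred from the last 2 sets. Differences between cultures are described without a test, since each culture was 1 array with no technical repeat. Alternatives covered the reference, the model, the threshold, the normalization between arrays, the choice of row per gene, a pseudocount and leaving out each culture in turn.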

Results

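Gene expression was measured in 3 primary cultures of human epididymis epithelial cells (cultures 1, 2 and 3), 1 array per culture, as the expression part of a study of open chromatin in these cells. The design holds no contrast between groups. The question the arrays could answer was which genes gave signal in these cells and how far the cultures differed. Of 17217 genes, 8722 (50.66%) gave log2 values above the olfactory receptor reference (limma, adjusted p under the threshold), and 9231 exceeded it in each of the 3 cultures. By construction, few olfactory receptors were called, 7 of 364. Of the 90 bitter taste receptor and keratin-associated protein genes, which played no part in that reference, 10 were called. These were also taken as silent for an alternative reference below. The reference itself was 8.99 in culture 1, 7.88 in culture 2 and 9.39 in culture 3. Values are given as mean log2 ± SD over the 3 cultures (n = 3), with adjusted p from limma's one-sided test. With an olfactory 99th percentile as reference 5661 genes were called, and with bitter taste receptor and keratin-associated protein genes 3451. The calls of EMX2, HOXA7, NR2F2, ACTA2, NEFL, FGB and COL1A2 below were lost with the last of these, though their means stayed above it, and those of RXRA, KRT5, BGN and CORO1A with either. The means of NR3C1, GATA3, SLC9A3, ATP6V1C2, NEFM, KLK10, PDZK1, UPK1B and ADAMTSL3 fell below both higher references. So did those of DST, ITGA6, KRT14 and KRT15. PTGDS, LSS, NLRP2, ANXA8, NIBAN1 and P4HA3 lost their calls with either, and their means fell below the last. Leaving out 1 array also moves the mean above the reference that a call needs, from 1.14 to 1.78 without culture 1, 0.82 without culture 2 and 1.46 without culture 3, because the SE follows the distance between the references that remain (0.889, 0.417 and 0.752).

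Epithelial genes were among those with the brightest signal. Of the 17 genes of simple epithelial identity, 16 were above the reference (16 when adjusted over the list alone), more often than other genes (Fisher's exact test, adjusted p = 0.000632). The keratin KRT8, an intermediate filament of simple epithelia, reached 15.06 ± 0.15, its relative KRT7 read 15.45, 14.72 and 14.82 in cultures 1, 2 and 3, and the junction protein plakoglobin (JUP) reached 15.02 ± 0.31. The adhesion proteins CDH1 (13.17 ± 0.42) and EPCAM (12.41 ± 0.82) and the keratin KRT19 (13.45 ± 0.75) were also called. ESRP1, an epithelial splicing regulator, was the member not called, at 8.59 ± 2.78. It read 5.53 in culture 1 and 9.31 and 10.94 in cultures 2 and 3. Of 12 basal epithelial genes 10 were called (10 over the list alone), which missed the threshold against other genes (Fisher's exact test, adjusted p = 0.0569). The laminin chains LAMA3 (14.32 ± 0.07) and LAMB3 (13.65 ± 0.21) and the integrin ITGB4 (13.18 ± 0.97) led this list. The basal keratin KRT5 was called at 11.02 ± 2.52 but not without culture 2, when its mean lay 0.79 above the reference, and TP63, a transcription factor of basal cells, was the lowest member at 3.55 ± 0.07. Without culture 1 the basal list had 6 called members, the 4 lost (DST, ITGA6, KRT14 and KRT15, named after their values were seen) lying 1.05 to 1.30 above the reference against 1.22 to 1.51 with all cultures.

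Transcription factors of the Wolffian duct, the embryonic origin of the epididymis, were called in 11 of 19 cases (11 over the list alone), a share that did not differ from other genes (Fisher's exact test, adjusted p = 0.755). SOX17 reached 13.48 ± 0.45 (adjusted p = 4.36e-15 by limma), SALL1 13.17 ± 0.64, PAX2 12.84 ± 0.28, PAX8 12.55 ± 0.29 and EMX2 12.14 ± 0.95. The lowest was EYA1 at 4.80 ± 0.24. GATA3 was called at 10.09 ± 2.48, with 7.30 in culture 1 against 12.03 in culture 2 and 10.96 in culture 3, and without culture 2 its mean lay 0.07 below the reference. Without culture 3 the mean stayed at 1.23 above it, against 1.34 with all cultures, and the call was lost to the larger SE. Of 15 measured genes of the posterior HOX list, regional patterning factors, 5 were called (5 over the list alone, adjusted Fisher p = 0.284). The list also holds genes of more central HOX groups, such as HOXA7 and HOXD8, and these make up most of the 5. HOXB9 (13.77 ± 0.25), HOXD8 (12.27 ± 0.52) and HOXA7 (11.73 ± 1.35) led, and HOXA13 was lowest at 4.40 ± 0.22.

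Among 17 nuclear receptors 8 were called (8 over the list alone; adjusted Fisher p = 0.883). With the olfactory 99th percentile 2 were called, and with taste receptor and keratin-associated protein genes 1. RARA, a retinoic acid receptor, reached 13.42 ± 0.11, NR2F2 12.10 ± 0.31, RXRA 10.92 ± 0.13 and the glucocorticoid receptor NR3C1 10.24 ± 0.26. Without culture 1 the mean of NR3C1 rose from 1.49 to 1.73 above the reference, and its call was lost only to the larger SE. Its mean lay below the olfactory 99th percentile (-0.025) and below the taste receptor and keratin-associated protein reference (-0.635). The estrogen receptor ESR1 (4.40 ± 0.35) and the progesterone receptor PGR (4.23 ± 0.26) lay below the reference in all 3 cultures.

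Genes of ion, bicarbonate and water transport were called in 12 of 24 cases (12 over the list alone; adjusted Fisher p = 1). With the olfactory 99th percentile 6 were called, and with taste receptor and keratin-associated protein genes 4. The sodium pump subunit ATP1B1 (14.16 ± 0.18) and the epithelial sodium channel subunit SCNN1A (13.49 ± 0.26) were among the brightest members. CFTR, the chloride and bicarbonate channel, was called at 12.09 ± 1.36 (adjusted p = 2.45e-08 by limma), with 13.31, 10.63 and 12.33 in cultures 1, 2 and 3. With taste receptor and keratin-associated protein genes as the reference its mean fell from 3.33 to 1.21 above it and the call was lost. The sodium-proton exchanger SLC9A3 was called at 10.09 ± 0.50, 1.33 above the reference. Its mean lay below the olfactory 99th percentile (-0.18) and below the taste receptor and keratin-associated protein reference (-0.79). Without culture 2 its mean fell to 0.67 above the reference and it was not called, while without culture 1 the mean rose to 1.71 and the call was lost only to the larger SE. The anion exchanger SLC26A3 was the lowest member at 3.85 ± 0.02. The water channel AQP9 was not called (9.65 ± 4.00, adjusted p = 0.115 by limma). It read 5.04 in culture 1, against 11.94 in culture 2 and 11.99 in culture 3, and without culture 1 it was called, 3.33 above the reference. Of 10 genes of clear cells, the proton-secreting cells of the epididymis, 1 was called, ATP6V1C2 at 10.26 ± 0.34 (1 over the list alone). This was fewer than among other genes (Fisher's exact test, adjusted p = 0.0179). With either higher reference 0 were called and the difference missed the threshold (adjusted Fisher p = 0.0655 and 0.300). With fewer genes called in all, a list of 10 could hardly pass it. The proton pump subunit ATP6V1B1 read 8.28 ± 0.10.

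Genes of secreted and sperm-coating epididymal proteins were mostly at or below the reference. Of 30 measured, 2 were called (2 over the list alone), fewer than among other genes (Fisher's exact test, adjusted p = 8.54e-06). The difference held with the olfactory 99th percentile (adjusted p = 0.000580). It missed the threshold with taste receptor and keratin-associated protein genes (1 member called, odds ratio 0.137, adjusted p = 0.0712). The 2 called with the main reference were NPC2, a cholesterol-binding protein, at 13.96 ± 0.10, and PTGDS, prostaglandin D synthase, at 10.44 ± 1.34. WFDC2, a secreted protease inhibitor, was not called at 9.82 ± 1.63 (adjusted p = 0.0665 by limma), with 7.93 in culture 1 and 10.73 and 10.79 in cultures 2 and 3. The chaperone CLU read 8.78 ± 0.48, the surface receptor ADGRG2 8.64 ± 1.71, the surface glycopeptide CD52 8.11 ± 0.70 and the sperm-binding protein CRISP1 5.28 ± 0.14, with PATE1 lowest at 4.09 ± 0.13. Without culture 2 the mean of PTGDS fell from 1.69 to 0.49 above the reference and 1 member, NPC2, was called. Without culture 1 WFDC2, then 2.12 above the reference, was called as well, making 3.

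**Figure D1:**
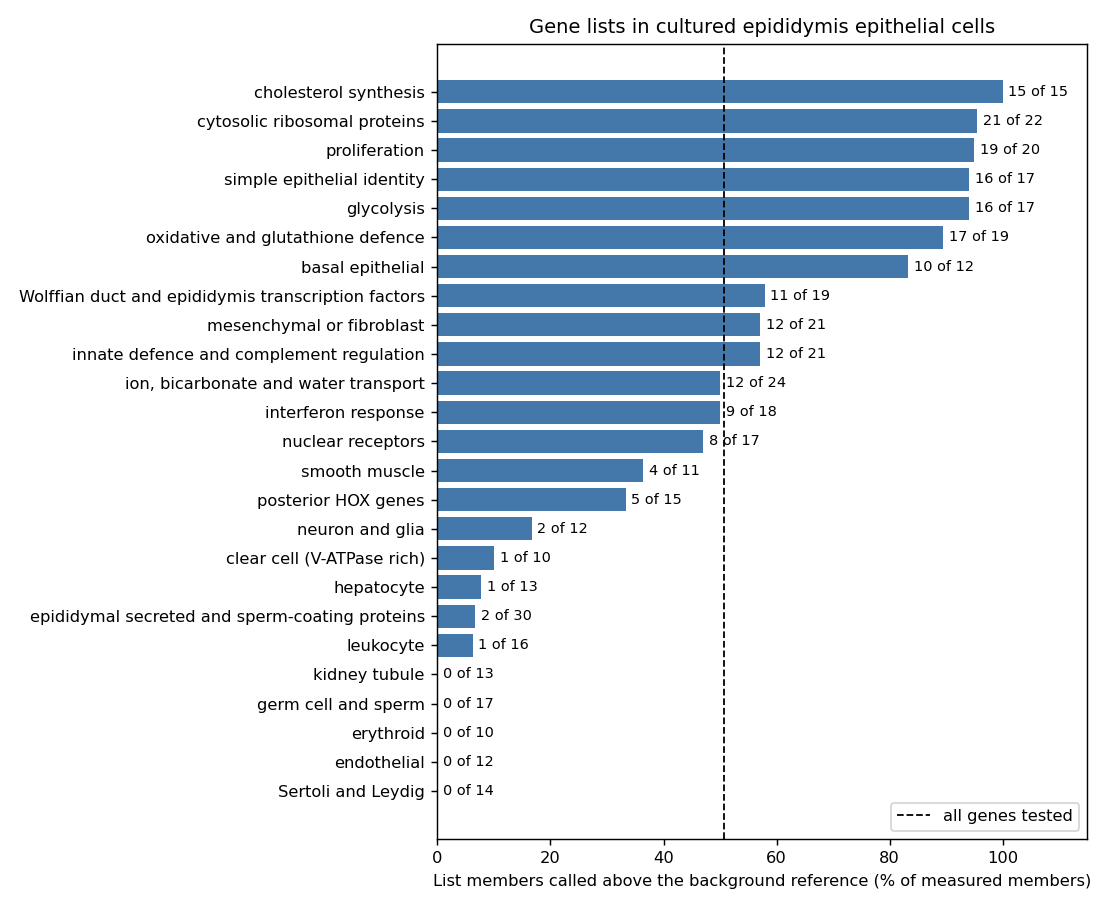
Horizontal bars give the percentage of each list's measured members called above the background reference in the 3 cultures, with the number called beside each bar, and the dashed line gives the 50.66% of all 17217 genes. Cholesterol synthesis stands at 15 of 15 and 5 lists of other cell types stand at 0.

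Defence genes were called in 12 of 21 cases (13 over the list alone; adjusted Fisher p = 0.755). The protease inhibitor SLPI (13.93 ± 0.59), the chemokine CXCL8 (13.53 ± 0.87) and the complement regulator CD46 (13.36 ± 0.09) led, while the defensin DEFB1 (5.41 ± 0.40) and the protease inhibitor PI3 (4.23 ± 0.09) lay below the reference. Interferon response genes were called in 9 of 18 cases (9 over the list alone; adjusted Fisher p = 1), with OAS2 lowest at 6.05 ± 0.29. With either higher reference 3 interferon genes were called. Growth and housekeeping lists stood high. All 15 cholesterol synthesis genes were called (adjusted Fisher p = 0.000257). So were 19 of 20 proliferation genes (adjusted Fisher p = 0.000252), among them CDC20 at 13.73 ± 0.44 and PCNA at 13.58 ± 0.34. The exception was MKI67 at 9.60 ± 0.78. The counts were 17 of 19 for oxidative and glutathione defence (adjusted Fisher p = 0.00154), 16 of 17 for glycolysis (0.000632) and 21 of 22 for ribosomal proteins (9.34e-05). Adjusting over each of these lists alone gave the counts just stated. The ribosomal protein RPLP0, used by every cell, read 7.36 ± 0.08, below the reference in all 3 cultures, so a low value here need not mean a missing transcript.

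Markers of other cell types split into 2 kinds. Of 21 mesenchymal or fibroblast genes 12 were called (12 over the list alone; adjusted Fisher p = 0.755). Vimentin (VIM, 15.37 ± 0.15) and the proteoglycans DCN (15.30 ± 0.40) and LUM (14.15 ± 0.69) lay in the top 3% of the signal distribution. The collagen COL1A1 was called at 12.74 ± 1.79, and TWIST1 was lowest at 3.71 ± 0.06. Of 11 smooth muscle genes 4 were called (4 over the list alone; adjusted Fisher p = 0.502), including TAGLN (14.57 ± 0.53) and ACTA2 (11.67 ± 0.29). The other lists had fewer called members than other genes. With taste receptor and keratin-associated protein genes as the reference, 0 lists passed the threshold for fewer. No member of these lists was called then (odds ratio 0 for each). Only 3451 of 17217 genes were called with it, so lists this small could hardly pass, and this setting cannot decide. The erythroid, hepatocyte and neuron and glia lists also missed the threshold with the olfactory 99th percentile (adjusted Fisher p = 0.0655, 0.114 and 0.176). Their odds ratios were then 0, 0.17 and 0.185. None was called of 12 endothelial (adjusted Fisher p = 0.000632), 10 erythroid (0.00164), 17 germ cell and sperm (7.55e-05), 14 Sertoli and Leydig (0.000252) or 13 kidney tubule genes (0.000365) by limma, nor at an unadjusted p under 0.05 (0 genes in each of the 5 lists). Requiring each culture to exceed its reference, with no model, gave INSL3 of the Sertoli and Leydig list and NPHS1 of the kidney list, both named after their values were seen. CDH5, an endothelial cadherin named for the same reason, was called without culture 2 (1.43 above the reference) or without culture 3 (1.94), against 0.66 with all cultures. One each was called of 16 leukocyte genes (CORO1A, 11.13 ± 0.07; adjusted Fisher p = 0.000632) and of 13 hepatocyte genes (FGB, 12.06 ± 1.74; adjusted Fisher p = 0.00288). Of 12 neuron and glia genes 2 were called, NEFL (12.01 ± 1.38) and NEFM (10.06 ± 2.03), and 1 over the list alone (adjusted Fisher p = 0.0326). The difference of this list from other genes was also lost without culture 1 (adjusted p = 0.121), without culture 2 (0.0613), with no model (0.122), with the highest row per gene (0.123) and with the common reference chosen after the values were seen (0.0655). Without culture 2 the mean of NEFM fell from 1.30 to 0.08 above the reference and its call was lost, while without culture 3 it stayed at 1.26 and the call was lost to the larger SE. The leukocyte gene PTPRC read 3.79 ± 0.47 and the hepatocyte gene ALB 4.70 ± 0.27.

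**Figure D2:**
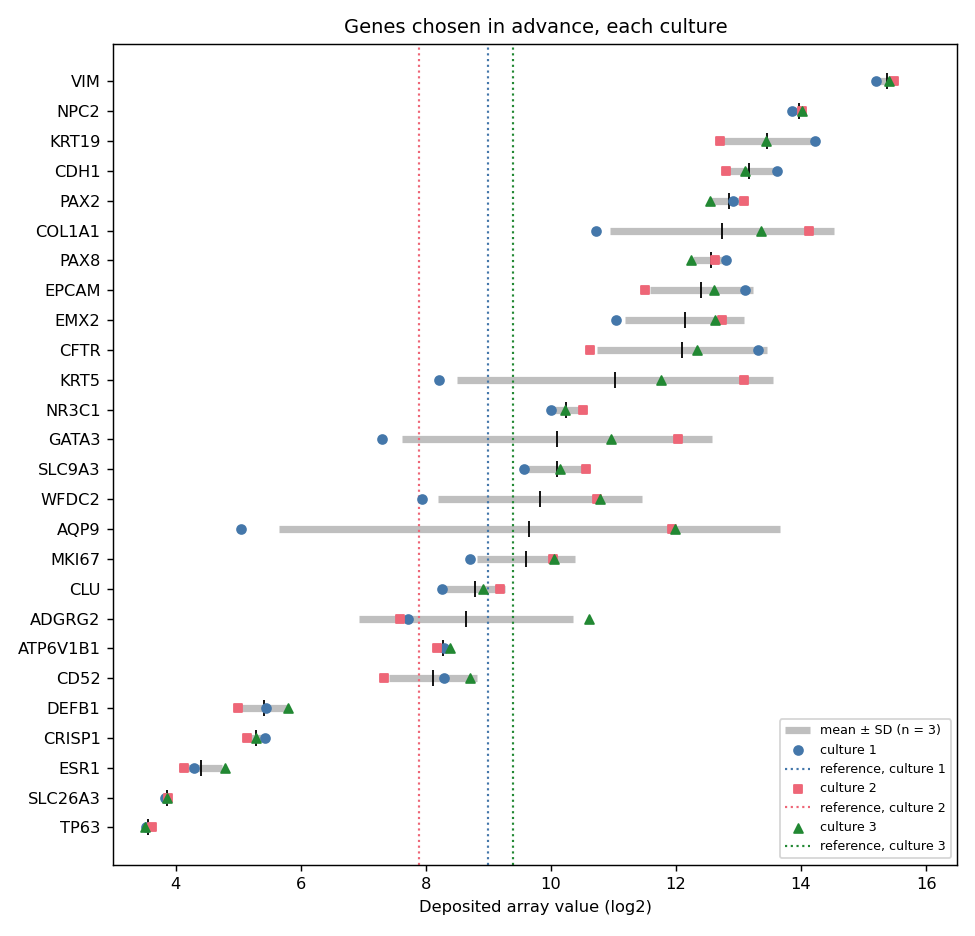
Points give the log2 value of each of 26 genes chosen in advance in cultures 1, 2 and 3, grey bars the mean ± SD, and dotted lines each array's background reference. AQP9, KRT5 and GATA3 lie below the reference in culture 1 and above it in cultures 2 and 3, while NPC2 and VIM lie far above it in all 3.

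The median percentile of signal placed 6 lists above 97.5% of random lists of the same size and 10 below. The posterior HOX list was among the 10 (median percentile 23.44), though its share of called members did not differ by Fisher's test. The clear cell list, with fewer called members, was not (24.74, above 2.94% of random lists). The simple epithelial list had a median percentile of 93.41, proliferation 78.52, glycolysis 99.31 and ribosomal proteins 99.25. The epididymal secreted protein list had 16.01 and the germ cell list 15.50. Among the 10 genes with the highest mean were RACK1, ACTB, ACTG1, IGFBP4, EEF2, PFN1, TMSB4X, CD24 and GAPDH, between 15.76 and 15.47. They include the actins, the growth factor binding protein IGFBP4 and the surface glycoprotein CD24, and the largest SD among them was 0.22.

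Across the 17217 genes the arrays correlated with Pearson r of 0.945 between cultures 1 and 2, 0.968 between cultures 1 and 3 and 0.959 between cultures 2 and 3 (Spearman rho 0.952, 0.967 and 0.969). Genes are not independent replicates, and no p-value is given. The median SD per gene was 0.201 for called genes and 0.463 for the others. A difference of more than 2-fold between the highest and lowest culture was seen in 2839 of the 12411 genes above the reference in at least 1 culture. This count held 1080 called genes. It was 1332 without culture 1, 1197 without culture 2 and 1863 without culture 3, and 1136 when a gene had to exceed the reference in each culture.

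The 10 called genes with the largest range between cultures had culture 1 at one end of the range. COL1A2, a type I collagen chain, read 7.93, 14.19 and 13.23 in cultures 1, 2 and 3, and the proteoglycan BGN read 8.20, 13.21 and 11.71. NIBAN1, P4HA3, a collagen prolyl hydroxylase subunit, NLRP2, PDZK1, a scaffold protein of brush border transporters, and ADAMTSL3 were also lowest in culture 1, at 6.65 to 7.58. ANXA8 (14.39, 8.03 and 10.05), the peptidase KLK10 (13.59, 7.25 and 9.97) and the urothelial membrane protein UPK1B (13.14, 7.80 and 9.14) were highest in culture 1. The calls of KLK10 and UPK1B rested on culture 1, and those of P4HA3, PDZK1 and ADAMTSL3 on culture 2, since without it each mean fell below the reference. ANXA8 lost its call without culture 1 (from 2.06 to 0.40 above the reference), as did BGN (2.28 to 0.76), NIBAN1 (2.07 to 0.67) and NLRP2 (1.62 to 0.69) without culture 2. Without culture 3 NLRP2 fell to 0.57 and NIBAN1 to 1.33, and neither was called. Only COL1A2 stayed called whichever culture was left out. With 1 common reference for the 3 arrays, chosen after the values were seen, a fit in which each gene's own spread enters, none of these 10 genes was called, nor were GATA3, KRT5 and NEFM.

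In all, 7 lists varied more between cultures than genes of the same signal, with a median SD above 97.5% of matched lists: simple epithelial identity (0.394), basal epithelial (0.504), Wolffian duct factors (0.532), ion, bicarbonate and water transport (0.641), innate defence (0.551), proliferation (0.484) and mesenchymal genes (0.544). Ribosomal proteins varied less (0.076). Without culture 1 the number of more variable lists was 3 and that of less variable lists 0, so the ribosomal proteins were no longer set apart. Without culture 2, 8 lists were more variable. Genes of 1 list can move together, while matched lists drew genes singly, so these placements are descriptions and not tests.

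**Figure D3:**
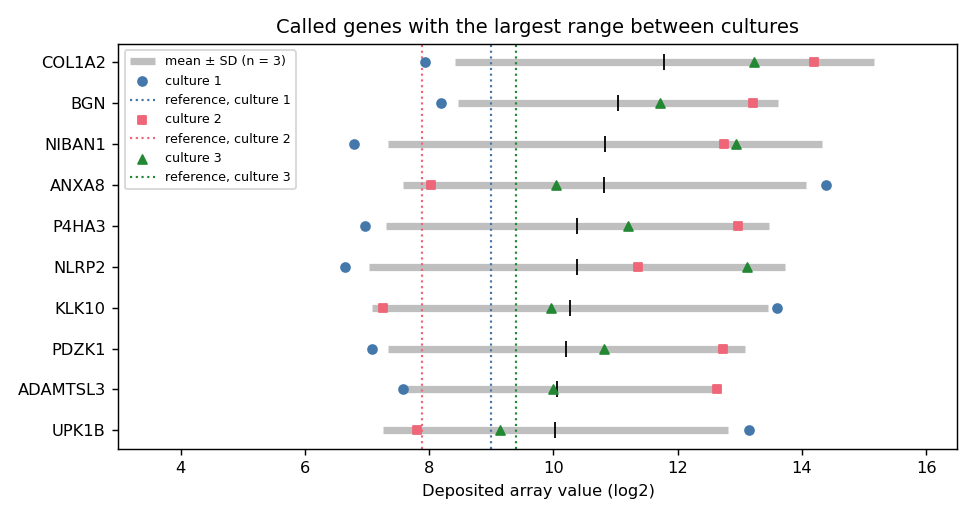
Points give the log2 value in cultures 1, 2 and 3 of the 10 called genes with the largest range, grey bars the mean ± SD, and dotted lines each array's background reference. COL1A2, BGN and NIBAN1 are lowest in culture 1, and ANXA8, KLK10 and UPK1B are highest there.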

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

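The table holds 4875 rows whose accession matched no gene symbol and that entered no test above. Of these, 1756 (36.02%) exceeded the olfactory receptor reference in all 3 cultures, a signal in rows that the comparisons did not use. These rows have no name here and no explanation was tested.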

How the results depend on the processing

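One alternative, a common reference for the 3 arrays, was chosen after seeing the data. Of 316 comparisons of a count, a list or a correlation with an alternative that could move, 259 stayed within their limit (1.5 times for a count). The number of called genes lay between 7779 and 8820 when 1 culture was left out, and was 8666 after quantile normalization, 9555 with the common reference and 9231 with no model. Centring the arrays cannot move any call or correlation, because the reference moves too, and these comparisons are not in the tally. It fell to 5661 with the olfactory 99th percentile and to 3451 with bitter taste receptor and keratin-associated protein genes, because a higher reference leaves fewer genes above it. With the 99th percentile 6 lists in place of 10 passed the threshold for fewer called members than other genes. The members called were 5 basal epithelial, 2 nuclear receptor, 6 transport, 0 clear cell, 1 epididymal secreted, 3 interferon, 0 leukocyte and 1 neuron and glia genes. Of the 8722 called genes 724 then had means below that reference, among them the named genes NR3C1 (-0.025), GATA3 (-0.176), SLC9A3 (-0.18), KLK10 (-0.002), PDZK1 (-0.06), UPK1B (-0.243), ADAMTSL3 (-0.208), ATP6V1C2 (-0.005), DST (-0.092), ITGA6 (-0.002), KRT14 (-0.282), KRT15 (-0.293) and NEFM (-0.215). The named genes KRT5, NLRP2, ANXA8, NIBAN1, P4HA3, BGN, RXRA, PTGDS, LSS and CORO1A stayed above it and lost their calls. With taste receptor and keratin-associated protein genes 0 lists passed the threshold for fewer called members, a setting in which small lists could hardly pass. The members called were 4 basal epithelial, 5 Wolffian duct, 2 posterior HOX, 1 nuclear receptor, 4 transport, 0 clear cell, 1 epididymal secreted, 3 interferon, 10 proliferation and 11 oxidative defence genes. They were 7 mesenchymal, 2 smooth muscle, 0 leukocyte, 0 neuron and glia and 0 hepatocyte genes. Of the 8722 called genes 1998 had means below that reference, among them the named genes NR3C1 (-0.635), GATA3 (-0.786), SLC9A3 (-0.79), NLRP2 (-0.502), ANXA8 (-0.06), KLK10 (-0.612), NIBAN1 (-0.056), P4HA3 (-0.499), PDZK1 (-0.671), UPK1B (-0.853), ADAMTSL3 (-0.818), ATP6V1C2 (-0.615), PTGDS (-0.439), LSS (-0.232), DST (-0.702), ITGA6 (-0.612), KRT14 (-0.892), KRT15 (-0.904) and NEFM (-0.825). The named genes CFTR, EMX2, KRT5, COL1A2, BGN, HOXA7, NR2F2, RXRA, ACTA2, CORO1A, NEFL and FGB stayed above it and lost their calls. With no model GATA3, KRT5, NEFM, DST and all but ANXA8 of the 10 genes with the largest range lost their calls, and 1 Sertoli and Leydig gene and 1 kidney tubule gene were called. At an adjusted p of 0.01 the calls of NR3C1, GATA3, SLC9A3, KLK10, PDZK1, UPK1B, ADAMTSL3, ATP6V1C2, NEFM, DST, ITGA6, KRT14 and KRT15 were lost, and the calls were 6 basal epithelial, 5 nuclear receptor, 0 clear cell and 1 neuron and glia genes. With the highest row per gene 2 hepatocyte genes were called. With the common reference 2 leukocyte, 1 germ cell, 1 Sertoli and Leydig and 1 kidney tubule genes were called. Leaving out 1 culture gave 6 to 8 basal epithelial, 1 to 3 epididymal secreted, 0 to 1 endothelial and 1 to 2 neuron and glia calls, 3 to 8 lists with more spread and 0 to 1 with less. The mean above the reference ranged from -0.032 to 2.585 for KLK10, -0.167 to 2.033 for UPK1B, -0.066 to 2.855 for GATA3, -0.105 to 3.447 for P4HA3, -0.245 to 3.132 for PDZK1 and -0.41 to 2.666 for ADAMTSL3. Over called genes only, Pearson r was 0.867 between cultures 1 and 2, 0.891 between 1 and 3 and 0.947 between 2 and 3, and on linear values it was 0.953 between 1 and 3 and 0.979 between 2 and 3. The count of genes differing over 2-fold was 4790 with no filter, 1136 above the reference in all cultures, 1123 among genes called with the common reference, 670 with a pseudocount of 1027.1 on the linear scale, and 1197 to 1863 when 1 culture was left out. The cause of the other changes was not tested. No paired analysis was possible because there is only 1 group. Dim genes limit what the arrays show, since the median SD was 0.463 among genes not called.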

Other observations

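The tests in this part that concern the arrays' floor and the fibroblast share, and the deviations of lists per culture, were chosen only after the values were seen. Several lists leaned one way in single cultures, each of which is 1 array. Outside 95% of lists matched on mean signal lay 4 lists below and 2 above in culture 1, 5 below and 2 above in culture 2, and 1 below and 6 above in culture 3. All 20 proliferation genes were highest in culture 3 and 19 were lowest in culture 1, with median deviations from the 3-culture mean of -0.45, -0.06 and 0.47 in cultures 1, 2 and 3. The deviations of cultures 1 and 3 lay outside all 10000 lists matched on mean signal. Proliferation genes can move together, while matched lists drew genes singly, so this placement is a description of single arrays. Of 17 glycolysis genes 16 were lowest in culture 1, by a median of 0.11 below the mean. Of 15 cholesterol synthesis genes 13 were highest in culture 1, by a median of 0.14. Of 17 nuclear receptors 13 were lowest in culture 1, with a median deviation of -0.42. In culture 2 the epididymal secreted protein list had a median deviation of -0.37 (20 of 30 lowest there), simple epithelial identity -0.12 and ion, bicarbonate and water transport -0.11. Of the 30 epididymal genes 28 were not called. The olfactory receptor genes assumed silent leaned the same way on that array (median deviation -0.63), so the epididymal lean cannot be read as lower expression.

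The olfactory receptor genes that set the reference were not alike on the 3 arrays. Of the 364 genes 318 (87.4%) were lowest in culture 2, with median deviations of 0.24, -0.63 and 0.42 in cultures 1, 2 and 3. A lower floor of that array would lower all dim genes alike. The 6072 other dim genes deviated by a median of 0.034 in culture 2, and 41% were lowest there. This argues against a shared floor as the cause of the gap between olfactory receptors and other dim genes in the deposited values. The unknown normalization could have removed a shift shared by all dim genes, so whether the floor itself differed cannot be told. The base composition of a gene's chromosome is argued against as the whole cause, since olfactory receptors lay below other dim genes of the same chromosome on all 10 chromosomes with at least 10 of them (median difference -0.526). Genomic DNA carried over into the RNA of cultures 1 and 3 is a candidate explanation. It would raise probes that match many near-identical genomic copies. In 30 dim members of such families not looked at before (SPANX, CT45A, XAGE, PSG and others), the median deviation in culture 2 was -0.766. This lay below all 10000 random dim lists. Of the 30, 22 were lowest in culture 2. PSG3, PSG11, RGPD1, VCX and SPANXN5 were highest there, the last barely (5.90 against 5.89 in culture 3). VCX2, VCX3B and CGB7 lay between the other cultures. Members of 1 family can read alike, while the random lists drew genes singly, so the placement overstates the evidence. DNA that raised all dim probes alike is argued against as the cause of the gap by the 0.034 of the other dim genes. Whether such a shared rise was present cannot be told, because the normalization is unknown and could have removed it. Whether olfactory receptor probes match several genomic copies was not examined. Weaker cross-hybridisation on that array, or the base composition of the probes themselves, would give much the same and stays open, and no biological explanation was tested.

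Only 2 of 30 epididymal secreted protein genes were called, and a reference raised on the arrays of cultures 1 and 3 could hide others. On the array of culture 2, whose reference was lowest (-0.87 from the mean reference), 7 members exceeded it (23.3%, 95% confidence interval 9.9 to 42.3%), among them WFDC2 and CLU, while 71.3% of all genes did. This argues against the raised reference as the main reason, although it is 1 array, and the members themselves lay lower there (median deviation -0.37), by less than the reference. Probes with a poor response, and a real loss of these transcripts in culture, stay open and were not tested.

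The mesenchymal genes leaned together, with 17 of 21 lowest in culture 1. A smaller share of fibroblasts in culture 1 is a candidate explanation that cannot be told apart from a change within the epithelial cells. The abundant fibroblast collagens COL3A1 (3.91 against 5.11 in culture 2) and COL6A3 (4.21 against 5.81) were lower in culture 1 too, but below the reference in all 3 cultures, as were 7 of the 21 in all, and a weak probe would look the same. COL1A2 was higher by 5.30 in culture 3 than in culture 1, while LUM was higher by 1.33 and DCN by 0.71, and DCN is close to the top of the scale. AQP9, GATA3 and KRT5, which are not in that list, were also lowest in culture 1. The smooth muscle genes did not follow, with 1 of 11 lowest in culture 1 and a median deviation of 0.20 there (TAGLN 15.13, 14.50 and 14.08 in cultures 1, 2 and 3). EPCAM, KRT19 and CDH1 were highest in culture 1, while the simple epithelial list as a whole had a median deviation of -0.003 there.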
